A study of Mus musculus with 7 samples.

How the data were processed

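Libraries came from sorted cortical microglia of 12-week-old C57BL/6 mice. Per the labels' protocols, meninges were removed, tissue was digested with trypsin, cells were captured with anti-CD11b beads and sorted on tdTomato and GFP, and 4 independent animals were used. Libraries were made with a Clontech kit for low input and sequenced as 50 bp single-end reads without strand, to the depth the labels give per replicate. Per the labels' protocols, the authors mapped reads with STAR 2.4.1c on GRCm38 with GENCODE release M5. The submitters' processing notes also name featureCounts, Subread and DESeq2, with no versions or settings. The deposited values are raw counts per gene symbol, and the filter that left 14616 rows is not given in the sources used here. Counts summed to between 5922972 and 7753577 per library, well below the number of reads the labels give. All counts are of PCR reads without molecular identifiers, so floors and intervals cover counting error only.

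Of the 14616 rows, 22 had names turned into date numbers by a spreadsheet. They named no gene and were left out of library sizes and tests, with a median of 0.133% of counts per library. Of the other 14594 rows, 139 were 0 in all libraries. Hoxb8 itself and mitochondrially encoded genes were not analysed here. The tdTomato reporter stays on in descendants of Hoxb8-expressing precursors, so a Hoxb8 level would not by itself check the labels. All 7 columns were mapped to samples by name. Groups were taken from the sorted cell type in the labels, and replicate numbers only name libraries.

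Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalisation, filterByExpr, robust glmQLFit and glmQLFTest) without an animal term, which left 11874 genes. P-values were adjusted by Benjamini-Hochberg at 0.05. The standard error is the log2 fold change divided by the square root of F. CPM were computed from the deposited counts with TMM factors. The common biological coefficient of variation was 0.460. A fold against a group at 0 is a lower bound, computed against 3 counts over the group. Gene lists were fixed before the data were examined (29 lists, 22 with 5 or more tested genes) and tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM (prior count 2), again with an estimated correlation, and with fry. The lists were homeostatic microglia, border-associated macrophage, marrow-derived brain macrophage, monocyte, neutrophil, lymphocyte, dendritic cell, red blood cell, neuron, astrocyte, oligodendrocyte, oligodendrocyte precursor, endothelial, mural and fibroblast, disease-associated microglia, interferon response, MHC class II, MHC class I, complement, cell cycle, dissociation and immediate early, inflammatory cytokine, lysosome, TGF-beta, transmitter and nucleotide receptors, Hox, mitochondrially encoded, cytosolic ribosomal and sex chromosome. Single values per library were compared by an exact two-sided permutation test over 35 splits in scipy 1.17.1. DESeq2 1.42.0 and limma-voom were alternatives, with other normalisations and filters, and each library was left out in turn.

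Genes named in the text followed a rule written before the data were examined. It took genes past the test without overlap between groups, with the genes of smallest p up to 10 in each direction where fewer than 5 passed, then Cx3cr1 and the sex chromosome list, then the first 3 tested members of each list and any member past the test. Genes called only with the pairing, DESeq2's lower calls and a few other list members (such as Stab1, Dab2, Cd74, H2-DMa, H2-DMb1 and H2-Oa) were named after their values were seen. One gene that the rule picks is not reported here.

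The labels do not say which libraries share an animal. Libraries with adjacent numbers (5 and 6, 13 and 14, 21 and 22) were therefore taken as possible pairs, with library 25 alone. Without a partner, library 25 adds nothing to the difference between groups in the fit with the pairs, while group means printed beside that fit include it. Their deviations from the group means correlated at 0.18, 0.28 and 0.19 across genes (0.17, 0.27 and 0.19 on autosomes). Each was over 0.1, the value set for accepting the pairs, and each Hoxb8 library correlated best with its own neighbour. The pairing comes from library numbers, not from a statement in the labels. Results of the fit with the pairs are given where they change a call.

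The gene test was checked on simulated counts for the 11874 genes, with 200 genes changed. Without pairs, 63.2% of 4-fold and 89.7% of 16-fold changes were recovered, with 14 false calls. That simulation drew all 7 libraries independently, with no structure shared between libraries, so it does not give the false calls to be found in data with such structure. With pairs, 74.0% and 93.6% were recovered, with 6 false calls. Gene positions are from GENCODE M21, of the same assembly, in which 14013 symbols matched.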

Results

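RNA was measured in microglia sorted from the cortex of 12-week-old mice that carried a green reporter in the Cx3cr1 locus, which marks microglia and related myeloid cells, and a red tdTomato reporter switched on for good in cells descended from Hoxb8-expressing precursors. Cells with both colours are called Hoxb8 microglia here (n = 3 libraries) and cells with green alone are called non-Hoxb8 microglia (n = 4 libraries). The deposited table held between 5922972 and 7753577 counts per library and between 13058 and 13750 genes with at least 1 count. Total counts lay between 7199948 and 7645745 in Hoxb8 libraries and over the whole of that range in non-Hoxb8 libraries, and no difference was detected in an exact two-sided permutation test (p = 0.457). With 3 libraries against 4, that test cannot give a p below 0.0571. All 7 were entered as separate libraries. No 2 agreed within sampling noise (chi-square per degree of freedom of 17.1 or more for each pair of libraries). This does not show that they are independent, since the labels name 4 animals for 7 libraries.

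The series compares Hoxb8 with non-Hoxb8 microglia, to ask whether microglia of the 2 origins differ in their transcripts. In all, 4 genes were higher in Hoxb8 libraries in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 11874 genes. Itga4, the integrin alpha 4 chain that leukocytes use to adhere to vessel walls, stood at 70.7 ± 36.9 CPM (TMM-normalised counts scaled to a common library total; SD, n = 3) in Hoxb8 libraries and 6.92 ± 3.02 (SD, n = 4) in non-Hoxb8 libraries, a log2 fold change of 3.36 ± 0.42 (SE, edgeR adjusted p = 0.0067). Plbd1, a phospholipase-like protein of myeloid granules, stood at 17.2 ± 9.89 against 0.213 ± 0.255 CPM (log2 fold change 6.20 ± 0.89, edgeR adjusted p = 0.020). Cd209a, a C-type lectin of monocyte-derived and dendritic cells, stood at 23.3 ± 27.4 against 0.155 ± 0.227 CPM (7.13 ± 1.05, edgeR adjusted p = 0.028). Cd300ld, an activating receptor of myeloid cells, stood at 34.3 ± 39.6 against 1.02 ± 0.331 CPM (5.07 ± 0.75, edgeR adjusted p = 0.028). In Hoxb8 replicate 2, Cd209a stood at 54.9 CPM (8.02 and 6.87 in the other Hoxb8 libraries) and Cd300ld at 79.8 (7.62 and 15.6), so the Hoxb8 means of both rest largely on it. None of the 4 overlapped between groups, and it follows that each was higher in the Hoxb8 library of all 3 pairs of libraries with adjacent numbers. In the GENCODE M21 annotation of GRCm38, protein-coding Itga4 spans chromosome 2 from 79255426 to 79333123, Plbd1 chromosome 6 from 136612070 to 136661928, Cd209a chromosome 8 from 3743397 to 3748984 and Cd300ld chromosome 11 from 114982274 to 114989922. Itga4 overlaps Cerkl on the opposite strand, and Cd209a and Cd300ld have close paralogs, so that reads without strand or shared with a copy leave part of these counts uncertain. All 4 calls were lost without non-Hoxb8 replicate 1 (0 genes called), and without Hoxb8 replicate 2, the library with the highest levels of all 4, 2 genes were called, of which only 1, Itga4, was among the 4. DESeq2 called 21 genes higher, among them Itga4, Plbd1 and Cd300ld but not Cd209a, for which it gave no adjusted p. Limma-voom called 0 genes, and leaving out the 3 libraries that held both Xist and Y-linked RNA also left 0.

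**Figure D1:**
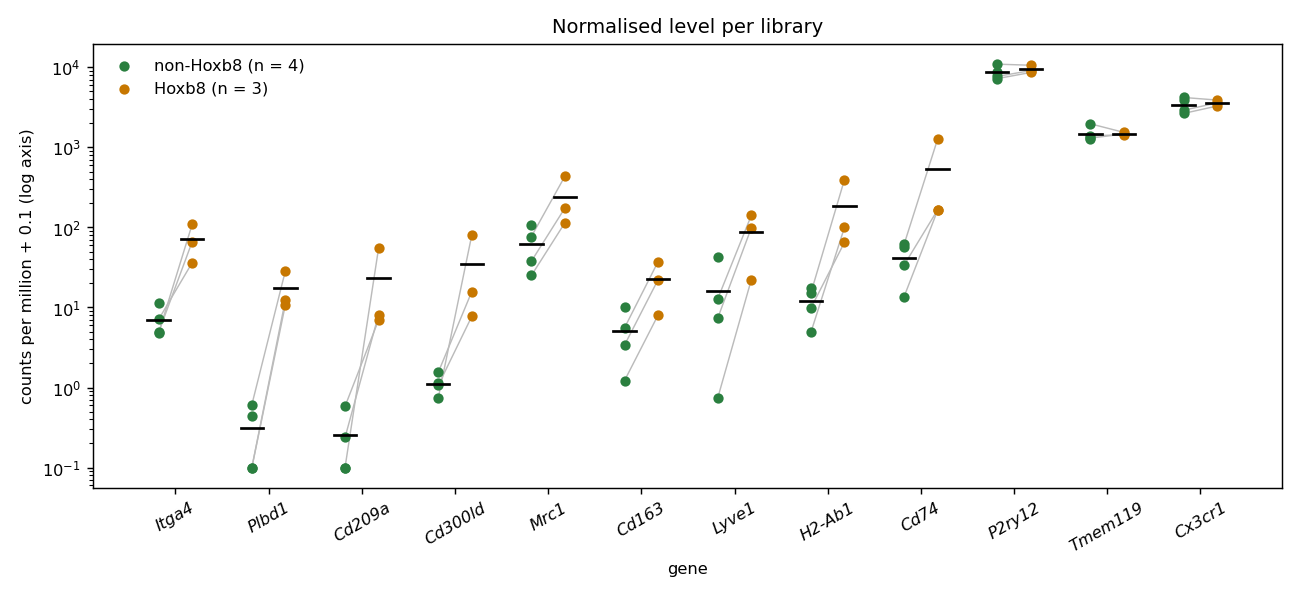
Normalised level (CPM + 0.1, log axis) of 12 genes in each library, with non-Hoxb8 libraries (n = 4) in green, Hoxb8 libraries (n = 3) in orange, black bars for group means and grey lines joining libraries with adjacent numbers. Itga4, Plbd1, Cd209a and Cd300ld, the genes past the test, and Mrc1, Cd163, Lyve1, H2-Ab1 and Cd74, which passed edgeR's test only with the pairing of libraries in the fit, lie higher in the Hoxb8 library of all 3 pairs. Cd163 and Lyve1 nevertheless overlap between groups, as do the microglial genes P2ry12, Tmem119 and Cx3cr1.

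The 6 next genes by p on the higher side did not pass in edgeR without pairs, while DESeq2 called all 6 (adjusted p from 2.5e-05 to 0.0076). With the pairs, edgeR called Spn, Clec12a and Clec4a1 (adjusted p = 0.0081, 0.0036 and 0.0032) but not Samd9l, Treml4 or Sh3pxd2b (adjusted p = 0.094, 0.14 and 0.15). Spn, the leukocyte sialoglycoprotein CD43, had 0 counts in the 4 non-Hoxb8 libraries together and 174 in the Hoxb8 libraries, at least 70.7-fold higher against a limit of 3 counts over the group (edgeR adjusted p = 0.098). Treml4, a receptor of non-classical monocytes, also had 0 counts in non-Hoxb8 libraries, at least 39.4-fold higher in Hoxb8 libraries (edgeR adjusted p = 0.35). Clec12a (log2 fold change 5.25 ± 0.97), Clec4a1 (2.39 ± 0.45), Samd9l (1.92 ± 0.40) and Sh3pxd2b (3.62 ± 0.79) had adjusted p-values from 0.12 to 0.35 in edgeR.

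No gene was lower in Hoxb8 libraries in edgeR's quasi-likelihood test at an adjusted p below 0.05, with 187 genes lower at an unadjusted p below 0.05, against 231 higher. DESeq2 called 5 genes lower (Adcy2, Btla, Fam172a, Gm14057 and Ptprg) and limma-voom 0. The genes lowest in p on that side were given no call by edgeR. Btla, an inhibitory lymphocyte receptor, stood at 0.224 ± 0.077 CPM (SD, n = 3) against 6.05 ± 5.58 (SD, n = 4; edgeR adjusted p = 0.65, DESeq2 adjusted p = 0.017). Gm14057, which overlaps 4930402H24Rik, had 0 counts in Hoxb8 libraries and 76 in non-Hoxb8 libraries, at least 20.8-fold lower. Fam172a stood at 34.2 ± 3.52 against 66.1 ± 5.08 CPM (edgeR adjusted p = 0.85). Ccser2, Ppargc1a, Ptprg, 2510003B16Rik, Depdc5 and Brpf3 had edgeR adjusted p-values above 0.98.

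Genes fixed beforehand as markers of border-associated macrophages, the macrophages of the meninges and perivascular space, had a median log2 fold change of 1.98 over 17 tested genes, 14 of them above 0. The list passed limma's camera with a preset correlation of 0.01 (adjusted p = 2.7e-12), and with an estimated correlation it did not (adjusted p = 0.24 with an estimated correlation). In edgeR 0 of the 17 passed over all genes tested and 7 when adjusted over the list alone, and DESeq2 called Clec12a (adjusted p = 9.2e-05) and Cbr2 (adjusted p = 0.045) over all genes. Mrc1, the mannose receptor, stood at 242 ± 172 against 61.4 ± 36.9 CPM (log2 fold change 1.98 ± 0.69), Cd163, a haemoglobin scavenger receptor, at 22.5 ± 14.7 against 4.96 ± 3.78 CPM (2.18 ± 0.65), and Lyve1, a hyaluronan receptor, at 87.3 ± 60.4 against 15.9 ± 18.8 CPM (2.46 ± 1.27). Stab1, which is also abundant in microglia, stood at 370 ± 45.3 against 380.2 ± 27.5 CPM. With adjacent library numbers as pairs, 8 of the 17 were higher over all genes tested and 11 when adjusted over the list alone. The 8 were Mrc1, Cd163, Lyve1, Cbr2, F13a1, Clec12a, Dab2 and Clec10a. The list of genes of marrow-derived brain macrophages, which shares Mrc1, Clec12a and Ms4a7 with it, had a median log2 fold change of 1.10 over 15 genes (camera adjusted p = 2.4e-07, and adjusted p = 0.18 with an estimated correlation). Of the 15, 0 passed in edgeR over all genes tested and 1 when adjusted over the list alone, with the pairs these numbers were 4 and 9, and DESeq2 without pairs called 1, Clec12a.

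Genes of MHC class II, which presents peptides to CD4 T cells, had a median log2 fold change of 2.34 over 8 tested genes (camera adjusted p = 4.3e-05, and adjusted p = 0.14 with an estimated correlation), and of 1.00 over 9 genes without the filter on low counts. In edgeR 0 passed over all genes tested and 3 when adjusted over the list alone, and with the pairs 4 passed in both counts. DESeq2 without pairs called H2-Ab1 (adjusted p = 0.00079) and H2-Eb1 (adjusted p = 0.017) over all genes. H2-Ab1 stood at 187 ± 182 CPM in Hoxb8 libraries against 11.8 ± 5.69 (log2 fold change 3.99 ± 0.81) and the invariant chain Cd74 at 535 ± 641 against 41.5 ± 22.2 CPM (3.69 ± 1.04). Library 14 stood apart in both, at 397 CPM for H2-Ab1 (65.1 and 100 in the other Hoxb8 libraries) and 1275 for Cd74 (164 and 166), so that the size of these changes rests largely on it. H2-Aa and H2-Eb1 were the other 2 called with the pairs. H2-DMa, H2-DMb1 and H2-Oa had log2 fold changes of -0.08, 0.09 and -0.08. The H2 genes are close paralogs, and Mir5107 lies within Cd74, so that their counts can share reads. The monocyte list had a median of 2.06 over 8 tested genes, the same with Treml4 at its lower bound (camera adjusted p = 9.0e-14), and was the only list called with an estimated correlation (adjusted p = 0.041), a call lost with the pairs (adjusted p = 0.35) and without the filter on low counts (adjusted p = 0.15, median 1.36 over 12 genes). Of its genes, 1 passed in edgeR over all genes tested (Itga4) and 6 when adjusted over the list alone, and with the pairs 3 (Itga4, Itgal and Lyz2) and 6. DESeq2 without pairs called 4 over all genes (Itga4, Treml4, Ccr2 and Lyz2). Ccr2, the chemokine receptor of classical monocytes, stood at 44.0 ± 9.14 against 16.7 ± 3.57 CPM (log2 fold change 1.40 ± 0.32, edgeR adjusted p = 0.46, DESeq2 adjusted p = 0.019). The dendritic cell list did not pass (median 0.16 over 9 genes, camera adjusted p = 0.13), with Cd209a its 1 member past edgeR's test over all genes, while Flt3, Zbtb46 and Xcr1 had log2 fold changes of 0.42, 0.39 and 0.38.

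Genes that define homeostatic microglia did not pass as a list (median log2 fold change -0.01 over 20 tested genes, camera adjusted p = 0.93) and 0 of 20 passed the gene test. The purinergic receptor P2ry12 stood at 9473 ± 1038 CPM in Hoxb8 libraries against 8694 ± 1663 in non-Hoxb8 libraries (log2 fold change 0.12 ± 0.15), Tmem119 at 1486 ± 48.2 against 1482 ± 331 (0.00 ± 0.16), the transcription factor Sall1 at 1201 ± 200 against 1262 ± 251 (-0.07 ± 0.17) and Cx3cr1, the reporter locus, at 3602 ± 306 against 3412 ± 740 (0.08 ± 0.16). These differences were smaller than their standard errors. Disease-associated microglia genes (median 0.07, 18 genes), interferon response (0.14, 14), MHC class I (0.20, 11), complement (0.04, 12), lysosome and phagocytosis (0.04, 20), TGF-beta pathway (-0.01, 12), receptors for transmitters and nucleotides (0.03, 12), cell cycle (0.01, 9) and cytosolic ribosomal proteins (-0.08, 28) had no member past the gene test, over all genes or adjusted over the list alone, and none of these lists passed camera. The same held for dissociation and immediate early genes (median -0.33, 18) and inflammatory cytokine genes (0.46, 17). Signs differed within 3 of these lists, with means of -0.02 for lysosome and -0.13 for receptor genes beside medians above 0, and a camera direction of down for cell cycle genes. With the pairs, Apoe and Axl of the disease-associated list passed over all genes. Adjusted over the list alone, the pairs gave 3 higher (Apoe, Axl and Igf1) and 1 lower (Csf1) in that list, 3 higher in the interferon response list (Ifi204, Cxcl10 and Ifitm3), 4 in the dissociation list (Fosb, Dusp1, Hspa1b and Nr4a1) and 5 in the inflammatory list (Il1b, Ccl7, Cxcl2, Ptgs2 and Cd83).

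Lists of other cells the capture could have carried along did not pass. The median log2 fold change was -0.33 for neurons (6 tested genes, mean -0.23, although camera's direction was up), -0.23 for astrocytes (11), -0.17 for oligodendrocytes (6) and -0.07 for endothelial cells (5). With the pairs in the fit the medians were 0.45 for neurons and 0.57 for astrocytes, both with camera's direction up and neither called (adjusted p = 0.13 and 0.14). In the pair of libraries 21 and 22 the median log2 ratio of Hoxb8 over non-Hoxb8 was 1.60 for neuron and 1.11 for astrocyte genes, beside 1.32 for the border-associated macrophage list. Lists with fewer than 5 tested genes were mural and fibroblast (4), Hox (3), lymphocyte (2), red blood cell (2) and neutrophil (1), with medians of -0.31, 0.03, 1.21, 0.77 and -0.16, and 0 genes past the test. Oligodendrocyte precursor and mitochondrially encoded lists had 0 tested genes.

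**Figure D2:**
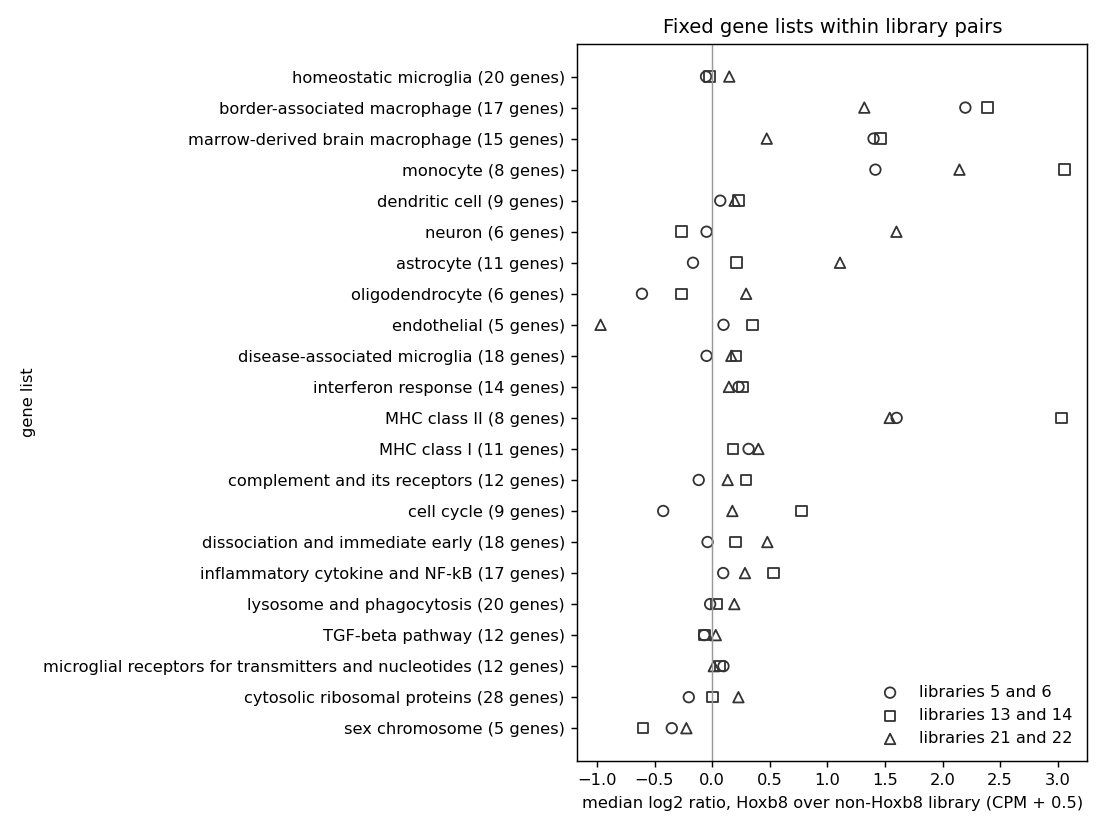
Median log2 ratio (CPM + 0.5) of Hoxb8 over non-Hoxb8 library within each of the 3 pairs of adjacent library numbers, for the 22 lists with 5 or more tested genes (1 symbol per pair). Border-associated macrophage, marrow-derived macrophage, monocyte and MHC class II lists lie between 0.47 and 3.06 in all 3 pairs, 5 other lists (dendritic cell, interferon response, MHC class I, inflammatory cytokine and receptor genes) also lie above 0 in all 3, between 0.01 and 0.53, and the homeostatic microglia list lies between -0.05 and 0.15.

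With adjacent library numbers as pairs in the fit, edgeR called 43 genes higher and 0 lower (358 higher and 238 lower at an unadjusted p below 0.05; DESeq2 with the pairs called 48 and 1, limma-voom 47 and 1). The 43 held the 4 genes above. All 43 were higher in the Hoxb8 library of all 3 pairs, which a call made from those same pairs favours. Of the 43, 40 were also called by DESeq2 and 35 by limma-voom with the pairs, 13 by DESeq2 without them, and 26 had no overlap between groups. Besides those named above, they were Spn, Clec4a1, Cybb, Tlr8, Ahnak, Adgre5, Msr1, Cd36, Mndal, Ifi203, Reps2, Cd93, Cd44, Vim, Myo5a, Mir5107, Cd38, Aoah, AI607873, Gas7, Il1b, Ccl7 and Cxcl2. Cybb, the catalytic chain of the phagocyte NADPH oxidase, stood at 99.8 against 7.53 CPM (log2 fold change 3.80 ± 0.34). Mndal and Ifi203 overlap, and their counts can share reads. Without the pair of libraries 13 and 14, 31 genes were higher and 7 lower, and 25 of the 43 kept their call, Itga4 and Plbd1 among them but not Cd209a and Cd300ld. The fit with all 3 pairs has 2 residual degrees of freedom, and library 25 adds nothing to its difference between groups. Camera with the pairs also called the dissociation and immediate early list (adjusted p = 0.033, up, where the fit without pairs gave down and no call) and the inflammatory cytokine list (adjusted p = 0.0089, up). With an estimated correlation their adjusted p-values were both 0.54, and no list passed.

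The first 3 principal components held 26.2%, 20.1% and 16.9% of the variance. The groups overlapped on components 1 and 3, and on component 2 they were apart by a small gap (Hoxb8 libraries from -27.9 to -11.4, non-Hoxb8 libraries from -11.2 to 81.6). Xist, the RNA of the inactive X, stood at 22542 and 14953 CPM in libraries 5 and 6 and at 23.2 and 15.1 in libraries 13 and 14, and the 4 Y-linked genes together at 0.412, 0, 293 and 269 CPM. Libraries 21, 22 and 25 held both (Xist 8537, 8291 and 14318 CPM, and Y-linked genes 133, 95.3 and 84.7 CPM). Xist and the 4 Y-linked genes did not pass the test between groups (list median -0.47, camera adjusted p = 0.81), and with the pairs Xist was lower when adjusted over the list alone (adjusted p = 0.026). Among inflammatory genes, Il1b stood at 408 and 943 CPM in libraries 13 and 14 and between 5.77 and 26.6 CPM in the other 5 libraries.

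**Figure D3:**
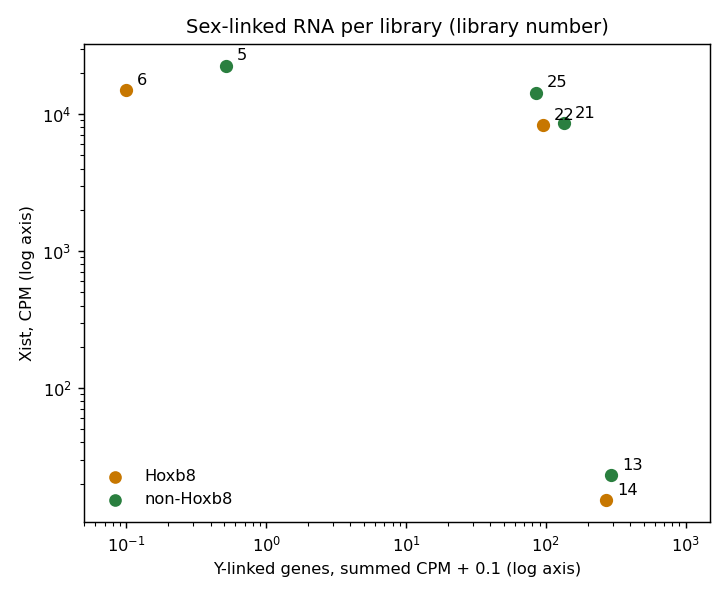
Xist (CPM, log axis) against the sum of Ddx3y, Eif2s3y, Kdm5d and Uty (CPM + 0.1, log axis) in each library, labelled by library number and coloured by group. Libraries 5 and 6 lie at high Xist with almost no Y-linked RNA, 13 and 14 the opposite, and 21, 22 and 25 have both.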

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

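The tests of mixed sex, of cells carrying both an inactive X and a Y, of carry-over and of the list content of another split were chosen after the values were seen. In the 4 non-Hoxb8 libraries, 126 measures were searched for 1 library far from the other 3. This found 7, where 6.3 are expected by chance.

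Of the 7, 3 concern the sex of the animals. Xist in replicate 2 was 23.2 CPM against 8537 to 22542 in the others (gap over range 0.858 on the log2 scale), Uty in replicate 1 was 0.137 CPM against 27.5 to 53.8 (0.851), and the mean log2 CPM of the sex chromosome list in replicate 1 was 1.78 against 5.84 to 6.64 (0.836). Libraries 21, 22 and 25 held both Xist and Y-linked RNA. Relative to the mean of libraries 5 and 6 for Xist and of libraries 13 and 14 for Y-linked genes, the 2 levels summed to at least 0.781 and at most 1.06 in these libraries, close to 1, as a mixture of cells from female and male animals would give, whereas cells that each carry an inactive X and a Y would give about 2. Carry-over of reads from libraries 13 and 14 would bring Il1b and Tnf along, and these stood at no more than 0.304 of the level it needs, that highest ratio being Tnf in library 25 and close to the bound set for exclusion, while Il1b stayed at or below 0.070. Pooled animals of both sexes, or mixing of cells before or during the sort, may therefore account for the pattern. These cannot be separated here. Under either, libraries 21, 22 and 25 would hold cells of more than 1 animal. Libraries may then not be separate by animal, within the groups or between the pairs. No biological explanation other than cells that carry both was tested.

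Il1b in replicate 2 (library 13) was 408 CPM against 5.77 to 11.1 CPM (gap over range 0.852), and its neighbour library 14 stood at 943 CPM. The split that set libraries 13, 14 and 25 against the other 4 called 90 genes, 86 of them higher in those 3. Of the 18 tested immediate early genes, 5 were among the 90 (Jun, Ier3, Zfp36, Klf6 and Btg2; hypergeometric adjusted p = 3.9e-06), as were 3 inflammatory genes (Ccl2, Ccl3 and Socs3; adjusted p = 0.0029) and 2 MHC class I genes (H2-K1 and H2-D1; adjusted p = 0.022). The hypergeometric test takes genes as independent. Genes of the immediate early and inflammatory lists were correlated within groups (0.888 and 0.819 as estimated by camera). The split was also picked for its number of calls, so these p-values are too small. Markers of other brain cells moved with this split too. The neuron, astrocyte and oligodendrocyte list means were higher in each of libraries 13, 14 and 25 than in any of the other 4. Camk2a, Aldoc and Mbp of these lists were among the 90 (hypergeometric adjusted p = 0.20, 0.27 and 0.20). The reason was not tested. A response to dissociation or activation that differs between animals is a candidate explanation, found and tested on the same data. Whether it arose in the animal or during digestion stays open, and no biological explanation was tested.

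The number of genes with a count was 13750 in non-Hoxb8 replicate 2 against 13058 to 13109 in the other 3 (gap over range 0.926). Ifit3 stood at 8.79 CPM in replicate 1 against 5.86 to 6.01 (0.938 on the log2 scale). Tgfbr1 stood at 3341 CPM in replicate 3 against 3638 to 3669 (0.911 on the log2 scale). Rows named by date numbers, which no comparison used, held a median of 0.133% of the counts.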

How the results depend on the processing

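The settings chosen after seeing the data were the pairing with DESeq2 or limma-voom, the pairing without each pair in turn, and the fit without libraries 21, 22 and 25. The 4 genes higher and 0 lower became 21 and 5 with DESeq2, which kept 3 of the 4, and 0 and 0 with limma-voom. Leaving out 1 library at a time gave 0 to 6 genes higher and 0 lower, with 0 without non-Hoxb8 replicate 1 and 2 without Hoxb8 replicate 2. The replicate block (adjacent library numbers as pairs) gave 43 genes higher and 0 lower, 48 and 1 with DESeq2, and 47 and 1 with limma-voom. Without libraries 5 and 6 it gave 63 and 5, without 13 and 14 31 and 7, and without 21 and 22 50 and 3, each with 2 pairs left. Without libraries 21, 22 and 25, 2 against 2 libraries gave 0 and 0. Other normalisations, filters and an adjusted p below 0.1 gave 4 or 5 genes higher and 0 lower. Besides the calls named with the results, the block in edgeR changed no call of a gene over all genes tested, and in camera with the preset correlation no call of a list. The cause of these changes was not tested, except that fewer libraries were tested where some were left out. The block also takes library 25 out of the difference between groups, and this was not separated from the pairing itself.

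In camera 4 lists passed, 1 with an estimated correlation, 1 with fry, 6 with the block and 10 with the block and limma-voom. Without the filter on low counts 6 passed, the same 4 and the lymphocyte and red blood cell lists (both up, adjusted p = 0.012), which had too few tested genes in the main test and did not pass with an estimated correlation (adjusted p = 0.29 and 0.37) or with fry. There the monocyte list also lost its call with an estimated correlation (adjusted p = 0.15), so that 0 lists passed that test, and the median log2 fold change moved from 2.06 to 1.36 for the monocyte and from 2.34 to 1.00 for the MHC class II list. The border-associated macrophage, marrow-derived macrophage and MHC class II lists lost their call only with an estimated correlation and with fry (fry adjusted p = 0.11, 0.11 and 0.091). Fry with the block called the border-associated macrophage (adjusted p = 0.036), MHC class II (adjusted p = 0.039) and complement lists (adjusted p = 0.036; 0.94 without it), all up, and the monocyte list lost its call (adjusted p = 0.088 against 0.010). With the block and limma-voom, camera also called the disease-associated (adjusted p = 0.0034), interferon response (adjusted p = 0.041) and MHC class I lists (adjusted p = 0.037) up and the sex chromosome list down (adjusted p = 0.0034). In limma's camera, the dissociation list turned from down without a call to up and called with the block (adjusted p = 0.033) and with the block and limma-voom (adjusted p = 0.0015). Without pairs it was called down without non-Hoxb8 replicate 3 (adjusted p = 7.7e-05) or without Hoxb8 replicate 2 (adjusted p = 0.00041). The inflammatory list was called up without Hoxb8 replicate 3 (adjusted p = 0.029) and turned from up without a call to down and called without Hoxb8 replicate 2 (adjusted p = 0.00067, the lowest with 1 library left out; the highest was an adjusted p of 0.959). The cause was not tested. At a mean CPM of at least 5 the monocyte list was too short to test. DESeq2 gives no list test, so none was run with it. Camera and fry used log2 CPM with a prior count of 2, and no other prior count was tried on those values. Genes near 0 counts in a group limit fold changes to the bounds given.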

Other observations

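The tests here were chosen after the results were seen, except the permutation tests of list means per library and the count of gene lists over other splits. Without pairs, the gene and list tests did not call the interferon response list, while camera with the block and limma-voom did (adjusted p = 0.041). Its per-library mean was 3.28 ± 0.087 log2 CPM in Hoxb8 libraries (SD, n = 3) and 2.84 ± 0.273 in non-Hoxb8 libraries (SD, n = 4), with no overlap (exact two-sided permutation p = 0.057, the smallest the design allows, adjusted p = 0.28 over 29 measures). Border-associated macrophage, marrow-derived macrophage, monocyte, dendritic cell and MHC class II means also did not overlap, with the same p. For border-associated macrophage genes the groups nearly touched, at 3.62 in non-Hoxb8 replicate 4 and 3.64 in Hoxb8 replicate 3. In the dendritic cell list Cd209a had a log2 fold change of 7.13, while the list median was 0.16.

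Of the 35 splits of the 7 libraries into 3 and 4, 2 gave at least the 4 genes of the real split, and the highest other gave 90, so chance cannot be excluded for the number of genes. That split (libraries 13, 14 and 25) calls many times the real number, which points to a structure of the samples. It keeps every pair together, and the 2 others that do (5, 6 and 25, and 21, 22 and 25) called 2 and 0 genes. Of the 8 splits that part all 3 pairs, only the real one called any gene. For gene lists, 15 of 35 splits gave as many as the 4 found, and the highest other gave 10, so chance cannot be excluded there either. With the pairs in the fit, 1 of the 4 possible swaps, the real one, gave 43 genes and the highest other 0, too few swaps for a share under 0.05.

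Border-associated macrophage genes were higher as a list in Hoxb8 libraries with camera's preset correlation but not with an estimated one (adjusted p = 0.24, and 0.32 with the pairs), while no difference was detected in homeostatic microglia genes. A lower share of microglia with all other brain cells raised alike stays open. Neuron, astrocyte and oligodendrocyte genes together had a median log2 fold change of -0.24 without pairs and 0.29 with pairs in the fit, against 1.98 and 2.31 for border-associated macrophage genes. In libraries 5 and 6, 13 and 14, and 21 and 22 their median log2 ratios were -0.20, -0.08 and 0.86, beside 2.20, 2.39 and 1.32 for macrophage genes. The rise that this explanation needs was thus seen only in the last pair. Within pairs the macrophage median exceeded that of the neuron, astrocyte and oligodendrocyte genes by 2.40, 2.47 and 0.46 on the log2 scale (mean 1.78 ± 1.14, SD, n = 3 pairs). The 95% interval of the mean, from -1.05 to 4.61, includes 0. A varying share of border-associated macrophages in the sorted cells also stays open. These macrophages carry Cx3cr1 and CD11b. They would fall in the Hoxb8 gate if they descend from Hoxb8-expressing cells, and in the gate for green alone if not. Within groups the 17 genes rose and fell together (mean correlation 0.475, above all of 10000 random lists). With the pairs in the fit their mean correlation was 0.081, at percentile 89.9 of random lists. That fit leaves fewer residual degrees of freedom and takes out library 25, so the drop does not show where the correlation lies. Homeostatic microglia genes reached percentiles 97.9 without and 95.8 with the pairs, and monocyte genes 89.7 and 96.5. In addition, 7 of the 17 stood above 10 CPM on average in non-Hoxb8 libraries too, where such macrophages could also be. The removal of meninges would take away part of such cells. For MHC class II genes, a share of 1 further cell type cannot be told apart from expression by the microglia themselves. Their correlation within groups lay at percentile 81.2 of random lists, and at 77.0 with the pairs. It averages all 8 tested genes, among them H2-DMa, H2-DMb1 and H2-Oa (log2 fold changes -0.08, 0.09 and -0.08), so it cannot decide for the 4 called with the pairs. Expression by Hoxb8 microglia, the biological difference that the design names, stays open and untested, as bulk RNA does not assign transcripts to cells.

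Spn and Treml4, which are high in patrolling monocytes, led to the hypothesis that such cells were in the gate. A further list of 16 genes of these cells, written before its own values were seen, had 9 tested genes, a median log2 fold change of 0.16 and a camera p of 0.223. With the pairs 1 of the 9, Adgre4 (17.5 against 5.74 CPM), passed when adjusted over the list alone. Of the 9, 6 (Gngt2, Pou2f2, Ceacam1, Cd300a, Bcl2a1b and Eno3) stood above 10 CPM on average in non-Hoxb8 libraries, which would hide a small share, so the test leaves the hypothesis open, and it may still hold.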
